A study of Eohaustorius estuarius with 21 samples.

How the data were processed

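Gene expression was measured in Eohaustorius estuarius, an estuarine burrowing amphipod used in sediment toxicity tests, on 21 custom Agilent arrays read in 1 colour (Cy3). Per the labels, total RNA came from animals preserved in RNAlater and was amplified and labelled with a low-input kit. The arrays form 7 groups of 3: an unexposed control, ammonia at 560 and 1000 ug/g, cypermethrin at 0.56 and 1.0 ug/kg, and deltamethrin at 0.18 and 0.32 ug/kg. Nothing in the labels says whether replicates came from separate exposure vessels or cultures, so each p-value measures the spread between samples.

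Per the file headers, the authors extracted the scanner images with Agilent Feature Extraction 10.7.3.1, which gave an intensity for each spot after background subtraction and spatial detrending. These deposited intensity values were not scaled between arrays. The deposited series table of the same arrays holds log2 values whose scaling is not given in the sources used here. Its values were compared with the scanner values. The correlation was at least 0.9999 on every array once the scanner values had been divided by the 75th percentile of each array and centred on each probe's median, and the median of every probe in the series table was 0.

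Each array carried 45220 spots, of which 43803 were not controls. These spots held 14723 probes for 8610 contigs (assembled transcript sequences). Of the contigs, 6113 had 2 probes and 2497 had 1. Spots marked by the extraction software as non-uniform or as population outliers (761 to 1754 per array) were left out, except in the 183 pairs of probe and array in which every spot was marked. The log2 intensities of a probe's remaining spots were averaged, and the 75th percentile of the array was subtracted. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 7922 of 14723 probes. The number of arrays limits the precision.

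Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group over the 21 arrays, 14 residual degrees of freedom and 3.19 prior degrees of freedom. The reported p-values are from limma's moderated statistics, 2-sided, and were adjusted within each comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures. The model was tested on simulated data with the arrangement of the comparison of deltamethrin 0.32 ug/kg with control. It recovered 4% of 100 probes changed by 1 on the log2 scale and 61% of 100 probes changed by 2, with 5 unchanged probes called. In 4 simulated runs without any change, 0 probes were called. The simulated probes varied independently of each other, so these runs do not cover calls that come from variation shared between probes, such as that of a slide.

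In all, 12 comparisons were made: each exposed group with control, the higher with the lower concentration of each chemical, cypermethrin with deltamethrin at the higher and at the lower concentrations, and both ammonia groups with cypermethrin at 0.56 ug/kg. The comparisons, filter, model, threshold and rule for naming probes were chosen before the data were examined. No annotation among the sources used here pairs the probes with gene names. The rule therefore named at most 2 contigs that were higher and 2 that were lower per comparison. Among probes that passed the test and did not overlap between groups, each contig was first represented by the probe with the highest mean over all arrays, and the contigs with the largest changes of these probes were named, so that another probe can show a larger change. Where a contig was well above background on no array of one group, no fold was given. Where too few passed, the rule took the probes with the smallest p, which are said not to pass. Not all of these are printed below. Gene lists and a set test (camera) had been planned and were not run, because they need gene names.

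Alternatives chosen before the data were examined were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter for probes well above background on all 21 arrays (2309 probes), slide as a random or fixed block, replicate number as a fixed block, only the compared groups in the model, array weights, the series table values, and leaving out each array in turn. For normexp, which ran on all spots with the control spots included, the median signal of a spot replaced the planned mean signal. It had first been run on probe averages, and that run is not reported. Further alternatives were chosen after seeing the data: leaving out the 2 arrays of slide 4, scan day as a fixed block, arrays of 1 scan day alone, slides 4 to 8 against slides 1 to 3 as a block, and the slide block fitted separately on slides 1 to 5 or on slides 6 to 8. The separate slide fits were run first. After their result had been seen, the planned fixed slide block was fitted over all 21 arrays, which keeps the other choices unchanged, and both are reported.

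Replicate numbers were tested as pairs. After group means were removed, arrays of different groups with the same number had a mean correlation of 0.0316, against -0.0165 for different numbers, and 7 of 21 arrays correlated best with their own number. The numbers were therefore not treated as pairs in the model. Slides were numbered 1 to 8 and scan days 1 to 4.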

Results

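Transcript levels of the amphipod were compared after exposure to ammonia and to 2 pyrethroid insecticides, with the stated purpose of finding effects and possible biomarkers of these exposures. Cypermethrin and deltamethrin are both pyrethroids with an alpha-cyano group, which act on the sodium channels of nerve cells, and deltamethrin carries bromine where cypermethrin carries chlorine. Each of the 7 groups held 3 arrays. The concentrations of the chemicals differed, so no comparison between chemicals was made at equal concentration. Contigs are given by their identifiers because nothing used here pairs them with gene names or genome positions.

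The arrays differed in signal, and the groups were not spread evenly over slides. The share of probes well above background ranged from 17.3% for replicate 2 of ammonia 560 ug/g to 69.6% for replicate 2 of deltamethrin 0.32 ug/kg. The dimmest 2 arrays, replicate 2 of ammonia 560 ug/g and replicate 2 of cypermethrin 0.56 ug/kg (27.7%), shared slide 4. Their rank correlations with the 19 other arrays were 0.650 to 0.804, against 0.815 to 0.958 among those 19. Controls lay on slides 1 to 3, and every array of cypermethrin 1.0 ug/kg and of deltamethrin lay on slides 6 to 8, so no slide held both control and any of these 3 groups. Ammonia and cypermethrin 0.56 ug/kg arrays lay on slides 2 to 5.

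**Figure D1:**
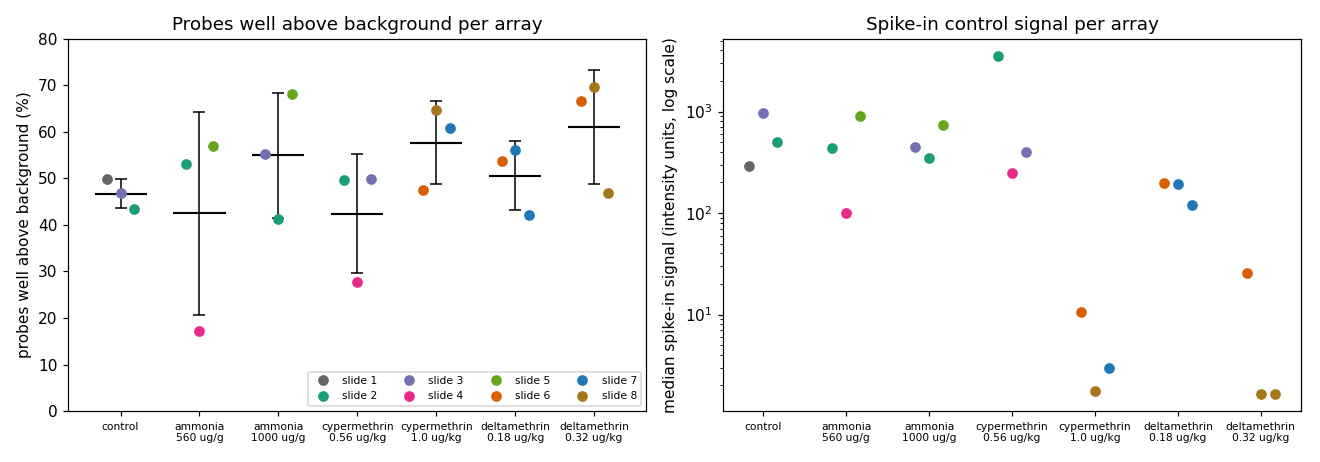
Left, the share of probes well above background on each array (percent), with the mean (bar) and SD (whiskers) of each group of 3; right, the median signal of the spike-in control probes on each array (intensity units, log axis). Points are arrays coloured by slide; the slide 4 arrays have the lowest shares, 17.3% and 27.7%, and the spike-in medians of replicates 2 and 3 of cypermethrin 1.0 ug/kg are 1.74 and 2.98, against 291 to 958 in the controls.

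Deltamethrin at 0.32 ug/kg was compared with control to find transcripts that respond to the higher concentration. Contig_5795 rose by 4.47 on the log2 scale (SE 0.64, adjusted p = 0.00161), from 0.55 ± 0.78 to 5.02 ± 0.39 (SD, n = 3), a 22.2-fold difference. Contig_4390 rose by 4.43 (SE 0.62, adjusted p = 0.00161), from -0.89 ± 0.89 to 3.54 ± 0.19 (SD, n = 3). Contig_8058 fell by 1.89 (SE 0.32, adjusted p = 0.00533), and contig_5396 fell by 1.75 (SE 0.30, adjusted p = 0.00588), from 4.43 ± 0.33 to 2.68 ± 0.11 (SD, n = 3). Contig_8058 lay below control in every other exposed group too, from -0.61 at cypermethrin 0.56 ug/kg to -1.65 at deltamethrin 0.18 ug/kg. Contig_5396 differed from control by -0.63 at ammonia 560 ug/g, -0.83 at ammonia 1000 ug/g and 0.0043 at cypermethrin 0.56 ug/kg. For each of these 4 contigs all 3 exposed arrays lay beyond all 3 controls, as the rule for naming required. Of the 39 probes called in limma, 38, with all 4 contigs, also differed in a comparison by slide. It set the mean of the 3 groups on slides 6 to 8 against that of control and ammonia. The same deltamethrin and control arrays enter it, so the overlap is not independent evidence. On those slides, the cypermethrin 1.0 ug/kg arrays differed from control by 0.72 for contig_5795 and 0.52 for contig_4390. For contig_8058 and contig_5396 they differed by -1.15 and -1.02, and none of these 4 differences passed the test. In limma, 34 probes rose and 5 fell, from 23 contigs, and 16 contigs were called by both of their probes. With normexp contig_4390 differed by 2.44 and contig_8058 by -0.47. No fall passed with normexp (26 rose, 0 fell) or with only the compared groups in the model (54 rose, 0 fell). The rises spanned 1.45 to 5.31 on the log2 scale, with a median of 4.03, and the falls spanned -1.89 to -1.26. Groups did not overlap for 22.1% of tested probes, against 10% by chance, and 1208 probes had an unadjusted p under 0.05. Spike-in medians were 25.8, 1.64 and 1.65 in this group. The number of calls was 25 without control replicate 3, 17 among probes well above background on all 21 arrays and 3636 with array weights (1625 rose, 2011 fell). It was 0 with scan day as a block and 0 with slides 4 to 8 against 1 to 3 as a block, both chosen after seeing the data. The scan days of the controls and of this group are linked only through the dim arrays of slide 4, so the scan day count rests on those arrays.

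**Figure D2:**
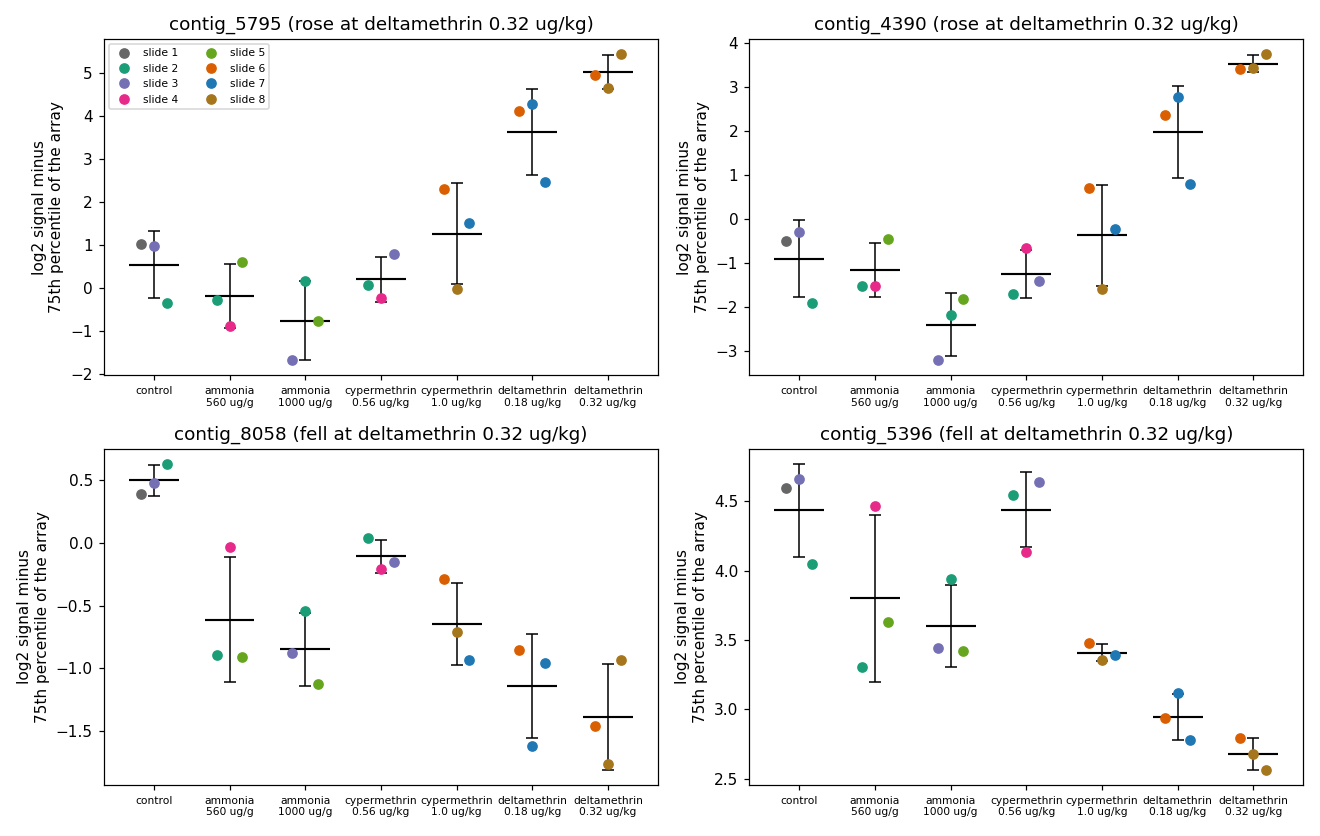
Values of the 4 contigs named for deltamethrin 0.32 ug/kg on each array (log2 signal minus the array's 75th percentile), by group, with points coloured by slide and the group mean (bar) and SD (whiskers, n = 3). Contig_5795 and contig_4390 have their highest group means, 5.02 and 3.54, at deltamethrin 0.32 ug/kg, where contig_8058 and contig_5396 have their lowest.

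Deltamethrin at 0.18 ug/kg was compared with control in the same way. Contig_4879 rose by 4.02 (SE 0.77, adjusted p = 0.0457), from 0.55 ± 1.21 to 4.57 ± 0.96 (SD, n = 3), and contig_5795 rose by 3.65 (SE 0.71, adjusted p = 0.0461). Contig_3952 fell by 2.72 (SE 0.50, adjusted p = 0.0447; well above background on 2 of the 3 exposed arrays), and contig_8058 fell by 1.65 (SE 0.32, adjusted p = 0.0461). All 3 exposed arrays lay beyond all 3 controls for these contigs, as the rule for naming required. With normexp the differences were 2.36, 1.47, -0.35 and -0.35 in this order, and none passed. Contig_5795 was represented here by another probe than at 0.32 ug/kg. The probe used at 0.32 ug/kg rose by 3.07 at 0.18 ug/kg and did not pass (adjusted p = 0.0619). The other probes of contig_4879, higher by 3.00 (adjusted p = 0.0619), and contig_3952, lower by 2.46 (adjusted p = 0.0570), did not pass either. In limma, 10 probes rose and 4 fell, from 12 contigs. All 14 also differed between the mean of the 3 groups on slides 6 to 8 and that of control and ammonia. That comparison uses the same deltamethrin and control arrays, so the overlap is not independent evidence. Groups did not overlap for 20.4% of tested probes, against 10% by chance. Of the 14 calls, 11 were also called at 0.32 ug/kg in the same direction, but both comparisons used the same 3 controls, so this is not independent evidence. The calls stood close to the threshold: the number was 0 without control replicate 1, control replicate 3 or deltamethrin 0.18 ug/kg replicate 2, 1 without control replicate 2, and 2 without deltamethrin 0.18 ug/kg replicate 1. It was also 0 with normexp, quantile normalization, no filter, slide as a random block, replicate as a block, scan day as a block, slides 4 to 8 as a block, or only the compared groups in the model, 7 without slide 4, and 538 with array weights.

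The 2 deltamethrin concentrations were compared with each other. Contig_5888 differed by 1.56 on the log2 scale between 0.32 and 0.18 ug/kg (adjusted p = 0.983) and contig_77 by -1.69 (adjusted p = 0.983), and neither passed the test. With normexp the differences were 0.14 and -0.70. Contig_5804, with a smaller p than contig_77, differed by -1.08 (SE 0.33, adjusted p = 0.983) and did not pass. In limma 0 probes passed, and 219 had an unadjusted p under 0.05. The groups were separate for 7.94% of probes, against 10% by chance. With array weights 1058 probes passed, with a weight of 35.4 for replicate 2 of deltamethrin 0.32 ug/kg, where the weights of the other 20 arrays were 0.2499 to 2.45.

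Cypermethrin at 1.0 ug/kg was compared with control. Contig_8409 was well above background on all 3 exposed arrays and on none of the controls (adjusted p = 0.175), so no fold is given. Contig_6334 differed by 1.51 (SE 0.31, adjusted p = 0.175), and contig_283 differed by -1.80 (SE 0.41, adjusted p = 0.175). For these contigs all 3 exposed arrays lay beyond all 3 controls, but none passed the test. With normexp contig_6334 differed by 0.31 and contig_283 by -0.76. Contig_8409 was also well above background on all 3 arrays at deltamethrin 0.18 and at 0.32 ug/kg. It passed against control in limma at both (adjusted p = 0.0457 and 0.0179). At these concentrations contig_6334 differed from control by 1.24 and 1.04, and contig_283 by -0.35 and -0.26, and none of these differences passed. No change passed in limma, with 0 probes called and 1077 at an unadjusted p under 0.05. Non-overlapping groups were found for 25.7% of probes, against 10% by chance. No slide held both control and cypermethrin 1.0 ug/kg arrays, so slide and exposure cannot be told apart here. Contig_8409 and contig_6334, but not contig_283, also differed in the comparison by slide described for deltamethrin 0.32 ug/kg. That comparison uses the same cypermethrin and control arrays. Spike-in medians were 1.74 and 2.98 in replicates 2 and 3 of this group, and that of replicate 1 also lay below every control (291 to 958). With only the compared groups in the model 138 probes passed, and with array weights 724 did.

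Cypermethrin at 0.56 ug/kg was compared with control. Contig_2633 differed by 1.79 on the log2 scale (SE 0.35, adjusted p = 0.707), from -0.44 ± 0.21 to 1.35 ± 0.40 (SD, n = 3), and contig_8141, well above background on 2 of the 3 exposed arrays, differed by -3.05 (SE 0.86, adjusted p = 1.00). Neither passed the test, and with normexp the differences were 1.01 and -1.75. Contig_327, with a smaller p than contig_8141, differed by -1.87 (SE 0.44) and did not pass. In limma 0 probes passed, and 255 had an unadjusted p under 0.05. For 10.8% of probes the groups did not overlap, against 10% by chance.

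The higher concentration of cypermethrin was compared with the lower. Contig_1820 was higher at 1.0 ug/kg by 3.20 on the log2 scale (SE 0.50, adjusted p = 0.0164), at 0.78 ± 0.25 against -2.42 ± 0.13 (SD, n = 3; well above background on 2 of the 3 arrays at 0.56 ug/kg), and its other probe passed as well (adjusted p = 0.0164). Contig_4416 was higher by 3.12 (SE 0.49, adjusted p = 0.0164), at 4.33 ± 0.10 against 1.21 ± 0.43 (SD, n = 3), and its other probe, higher by 3.05, did not pass (adjusted p = 0.0501). With normexp contig_1820 differed by 1.21 and passed, and contig_4416 did not (adjusted p = 0.147). All 3 arrays at 1.0 ug/kg lay above all 3 at 0.56 ug/kg for both, as the rule for naming required. Contig_441 differed by -3.59 (SE 0.72) and contig_6357 by -1.92 (SE 0.39), each with an adjusted p of 0.0501, and did not pass. At 1.0 ug/kg both were well above background on 2 of the 3 arrays, and with normexp the differences were -0.89 and -0.55. In limma these 3 probes were the only ones that passed, all higher, and 1494 had an unadjusted p under 0.05. All 3 also differed between the mean of the 3 groups on slides 6 to 8 and that of control and ammonia. That comparison uses the same cypermethrin 1.0 ug/kg arrays. The 2 cypermethrin groups shared no slide, so slide and concentration cannot be told apart here. Cypermethrin 0.56 ug/kg also differed from deltamethrin 0.18 ug/kg, on slides 6 and 7, by -2.85 for contig_1820 and -2.45 for contig_4416, and both passed. Groups did not overlap for 31.6% of probes, against 10% by chance. The number was 0 without any 1 of the 6 arrays, without slide 4, with no filter, or with slides 4 to 8 as a block. With scan day as a block 2 probes passed, both lower and neither among these 3. The number was 10 with normexp, 37 among probes well above background on all arrays, 43 with the series table, 78 with quantile normalization, 163 with replicate as a block, 217 with only the compared groups, and 1234 with array weights.

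Cypermethrin at 1.0 ug/kg was set against deltamethrin at 0.32 ug/kg, the higher concentration of each pyrethroid. Contig_2743 was lower in cypermethrin arrays, with a log2 difference of -7.02 (SE 1.29, adjusted p = 0.00916), at -1.97 ± 3.96 against 5.05 ± 0.35 (SD, n = 3). Contig_7650 was lower as well, with a difference of -6.90 (SE 1.27, adjusted p = 0.00916), at -2.40 ± 3.78 against 4.50 ± 0.20 (SD, n = 3). All 3 cypermethrin arrays lay below all 3 deltamethrin arrays for both, as the rule for naming required. Neither contig was well above background in cypermethrin replicate 2, so the size of these differences includes a value at background. With normexp they were -4.17 and -3.65, and both passed. Leaving out 1 array moved them between -8.84 and -4.91 for contig_2743 and between -8.79 and -5.01 for contig_7650, and both calls ended without cypermethrin replicate 2 or deltamethrin replicate 3. In limma 54 probes from 31 contigs were lower with cypermethrin and 0 were higher, with 812 at an unadjusted p under 0.05. Groups did not overlap for 19.9% of probes, against 10% by chance. Of the 34 probes that rose at deltamethrin 0.32 ug/kg, 29 were among these 54, but both lists rest on the same 3 deltamethrin arrays, so the overlap is not independent evidence. Within slide 6 the difference of contig_2743 was -3.22, and the median over the 54 probes, which were chosen on these arrays, was -2.92. Within slide 8, which held cypermethrin replicate 2, these values were -11.3 and -5.60. With slide as a fixed block over all arrays 60 probes passed, 51 of them shared, whereas the slide block fitted on slides 6 to 8 alone, which uses fewer arrays, gave 0. The number was 6 without cypermethrin replicate 2, 35 without deltamethrin replicate 3 or with normexp, 19 with probes well above background on all arrays, 0 with only the compared groups, and 2340 with array weights.

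**Figure D3:**
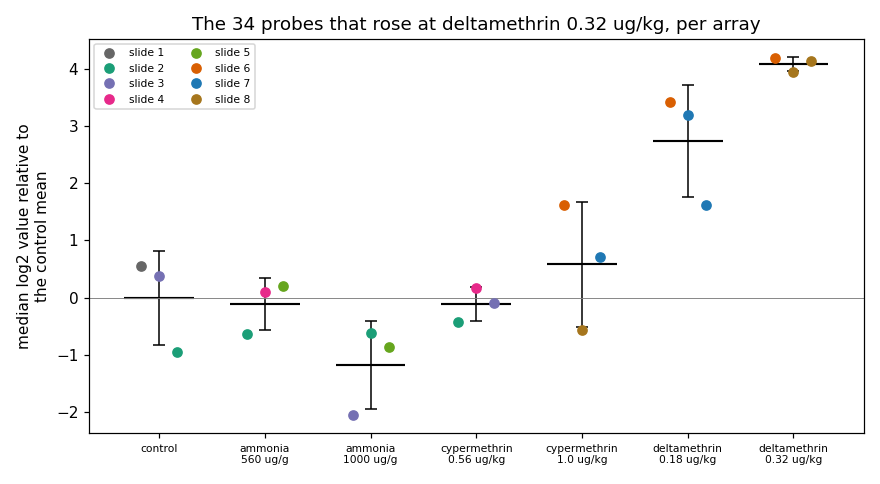
Median over the 34 probes that rose at deltamethrin 0.32 ug/kg, on each array (log2, relative to the control mean), by group, with points coloured by slide and the group mean (bar) and SD (whiskers, n = 3). The mean is 4.09 at deltamethrin 0.32 ug/kg, for which the probes were chosen, 2.75 at deltamethrin 0.18 ug/kg, 0.59 at cypermethrin 1.0 ug/kg and between -1.18 and -0.01 in the other groups.

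Cypermethrin at 0.56 ug/kg was set against deltamethrin at 0.18 ug/kg, the lower concentration of each. Contig_4735 was lower in cypermethrin arrays, with a log2 difference of -3.58 (SE 0.56, adjusted p = 0.0160), at -0.37 ± 0.25 against 3.21 ± 0.72 (SD, n = 3), and contig_5659 with a difference of -3.54 (SE 0.57, adjusted p = 0.0160). Contig_441 was higher by 4.19 (SE 0.71, adjusted p = 0.0171) and contig_515 by 3.12 (SE 0.56, adjusted p = 0.0228). The other probe of contig_515, higher by 1.99, did not pass (adjusted p = 0.255), while those of the other named contigs did. Contig_441 was well above background on 1 of the 3 deltamethrin arrays and contig_515 on 2, so these sizes include values at background, and with normexp contig_441 differed by 0.76, contig_515 by 1.26, contig_4735 by -1.61 and contig_5659 by -1.49, and none passed. Contig_5659 was well above background on 2 of the 3 cypermethrin arrays. All 3 arrays of one chemical lay beyond all 3 of the other for these contigs, as the rule for naming required. In limma 7 probes were higher and 22 lower with cypermethrin, from 19 contigs, and 15 of the 22 were among the probes that rose at deltamethrin 0.32 ug/kg. Of the 29 probes, 26, with all 4 contigs, also differed in the comparison by slide. It set the mean of the 3 groups on slides 6 to 8 against that of control and ammonia, with the same deltamethrin arrays. Cypermethrin 1.0 ug/kg differed from deltamethrin 0.32 ug/kg by -3.94 for contig_4735 and -4.09 for contig_5659. All arrays of that comparison lay on slides 6 to 8, but slide was not in its model. Contig_441 and contig_515 were not called there. The balance of directions turned on single arrays: 13 were higher and 12 lower without cypermethrin 0.56 ug/kg replicate 2, 6 and 0 without deltamethrin 0.18 ug/kg replicate 1, and 1 and 25 without deltamethrin 0.18 ug/kg replicate 3. For 22.8% of probes the groups did not overlap, against 10% by chance. The 2 groups shared no slide, and each of the 6 arrays, when left out, ended the call of at least 1 of these 4 contigs. The number was 0 without cypermethrin 0.56 ug/kg replicate 1 or deltamethrin 0.18 ug/kg replicate 2, and 7 without cypermethrin 0.56 ug/kg replicate 3. It was 0 with normexp, 20 with scan day as a block (10 higher, 10 lower, 7 shared), 3 with slides 4 to 8 as a block, 7 with no filter, 15 among probes well above background on all arrays, 16 without slide 4, 61 with replicate as a block, and 695 with array weights.

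Ammonia at 1000 ug/g was compared with control. Contig_77 differed by 2.23 on the log2 scale (SE 0.52, adjusted p = 0.705), from 0.67 ± 0.62 to 2.90 ± 0.81 (SD, n = 3). Contig_6339 differed by -2.57 (SE 0.46, adjusted p = 0.2502), from -0.05 ± 0.37 to -2.62 ± 0.33 (SD, n = 3). All 3 exposed arrays lay beyond all 3 controls for both, and neither passed the test. Contig_6339 was well above background on 2 of the 3 exposed arrays, and with normexp contig_77 differed by 1.09 and contig_6339 by -0.59. No change passed in limma, with 0 probes called and 305 at an unadjusted p under 0.05. Separate groups were seen for 10.9% of probes, against 10% by chance. With array weights 1 probe passed.

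Ammonia at 560 ug/g was compared with control. Contig_1822 was well above background on 1 exposed array and on none of the controls (adjusted p = 1.00), so no fold is given. Contig_3323 differed by -2.43 (SE 0.64, adjusted p = 1.00), from 2.66 ± 0.32 to 0.23 ± 1.42 (SD, n = 3), and with normexp by -1.58. Neither passed the test. In limma 0 probes passed, and 307 had an unadjusted p under 0.05. Non-overlapping groups made up 6.92% of probes, against 10% by chance. Without control replicate 1, or with scan day as a block, 1 probe passed.

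The 2 ammonia concentrations were compared with each other, and both together with cypermethrin 0.56 ug/kg. Between 1000 and 560 ug/g, contig_6051 differed by 2.15 (SE 0.57, adjusted p = 0.878) and contig_24 by -1.21 (SE 0.33, adjusted p = 0.878), relative to a median over all probes of -0.23, which was -0.01 with quantile normalization. With normexp contig_6051 differed by 0.97 and contig_24 by -0.99. In limma 0 probes passed, 315 had an unadjusted p under 0.05, and groups did not overlap for 8.80% of probes, against 10% by chance. Between the 6 ammonia arrays and the 3 arrays of cypermethrin 0.56 ug/kg, contig_77 differed by 2.38 (SE 0.45, adjusted p = 0.221) and contig_2633 by -1.74 (SE 0.30, adjusted p = 0.196), or by 1.18 and -0.96 with normexp. No change passed in limma, with 0 probes called and 577 at an unadjusted p under 0.05. Groups did not overlap for 2.61% of probes, against 2.38% by chance.

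Fold changes against control were correlated across the 7922 probes, which are not independent replicates. Pearson's r was 0.71 between the 2 deltamethrin concentrations (jackknife SE over arrays 0.246), 0.20 between the 2 cypermethrin concentrations (SE 0.282), and 0.42 between the 2 ammonia concentrations (SE 0.381). Between cypermethrin 1.0 and deltamethrin 0.32 ug/kg it was 0.41 (SE 0.318), between cypermethrin 0.56 and deltamethrin 0.18 ug/kg 0.21 (SE 0.352), which turned to -0.22 with normexp, and between ammonia 1000 ug/g and deltamethrin 0.32 ug/kg 0.37 (SE 0.314). All of these comparisons shared the same 3 controls. In 100 simulated draws with shared controls and no effect, the mean r was 0.499, with a range of -0.207 to 0.850, so each of the 6 values lay within the range that shared controls alone gave.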

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

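Tests chosen after the result was seen were the splits, those on the 34 risen probes, a batch shared by slides 4 to 8, replicate number 3 as a source, the blocks on scan day and on slides 4 to 8, and the counts without slide 4.

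Differences between exposed groups that were tested directly gave 54 probes between cypermethrin 1.0 and deltamethrin 0.32 ug/kg, 29 between cypermethrin 0.56 and deltamethrin 0.18 ug/kg, and 3 between the 2 cypermethrin concentrations. Leaving out 1 array changed each of these: 54 became 6 without cypermethrin 1.0 ug/kg replicate 2 and 35 without deltamethrin 0.32 ug/kg replicate 3. The 29 became 0 without cypermethrin 0.56 ug/kg replicate 1 or deltamethrin 0.18 ug/kg replicate 2, 6 without deltamethrin 0.18 ug/kg replicate 1 and 7 without cypermethrin 0.56 ug/kg replicate 3, and the 3 became 0 without any 1 of the 6 arrays. The spike-in probes, which no comparison uses, had a median of 3541 on cypermethrin 0.56 ug/kg replicate 1, above every control (291 to 958).

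Regrouping the same arrays gives 10 splits for each comparison of 3 against 3, which is too few for a share under 0.05. The real split and the highest of the other splits called 14 and 0 probes for deltamethrin 0.18 ug/kg and 39 and 0 for deltamethrin 0.32 ug/kg against control. The counts were 3 and 0 between the cypermethrin concentrations, 54 and 0 between the pyrethroids at the higher concentrations and 29 and 0 at the lower, so in these 5 comparisons 1 split, the real one, gave as many. In the other comparisons the real split called 0, and the highest other was 111 for ammonia 560 ug/g, 0 for ammonia 1000 ug/g, 8 for cypermethrin 0.56 ug/kg and 1 for cypermethrin 1.0 ug/kg against control. It was 0 between the deltamethrin concentrations and 533 between the ammonia concentrations. The last of these parted slides 2 and 3 from slides 4 and 5 and points to a structure of the samples. With slide as a fixed block that comparison had 0 calls. For both ammonia groups against cypermethrin 0.56 ug/kg, 84 of 84 splits gave as many as the real count of 0, and the highest, 484, set the ammonia arrays of slides 4 and 5 apart.

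The 34 probes that rose at deltamethrin 0.32 ug/kg lay on slides apart from the controls. With slide as a block, these probes were 2.83 higher on the log2 scale (SE 0.691) in deltamethrin than in cypermethrin 1.0 ug/kg arrays. All 6 deltamethrin arrays lay above the cypermethrin array of their slide. The 0.32 ug/kg arrays had chosen the probes, which inflates this difference. The 0.18 ug/kg arrays, not used in the choice, lay at 3.42 against 1.61 on slide 6. On slide 7 they lay at 1.63 and 3.19 against 0.71, so slides 6 to 8 as the whole cause are argued against. Between deltamethrin and cypermethrin arrays whose spike-in median was under 5, the gap was 3.24 (control SD 0.820). These deltamethrin arrays, replicates 2 and 3 of 0.32 ug/kg, had helped choose the probes, so the gap cannot decide about labelling. The cypermethrin arrays, replicates 2 and 3 of 1.0 ug/kg, took no part in the choice. They lay at -0.57 and 0.71, against -0.95 to 0.55 in the controls. The deltamethrin 0.18 ug/kg arrays, with spike-in medians of 119 to 198, lay at 1.63 to 3.42. These values argue against labelling with little spike-in signal as the whole cause. Normalization or background correction as the whole cause is argued against by a median log2 fold change of 2.62 with normexp and 3.96 with quantile normalization, against 4.03. The probes were chosen for their rise on these same arrays, and the lower value with normexp shows that its size depends on background correction. The calls ended with scan day as a block, where the median was 4.75 with a median SE of 1.06, and with slides 4 to 8 as a block, where it was 3.59 with 0.845, against 4.03 with 0.642 before, so the error was larger in both and the fold was smaller in the second. A response to deltamethrin is a candidate explanation, as a hypothesis found and tested on the same data, and a contribution of slide to its size stays open.

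A set of 619 probes differed between the mean of the 3 groups on slides 6 to 8 and that of control and ammonia. Of these, 447 were higher on slides 6 to 8, with a median shift of 1.19 over the set, and without slide 4 the set held 488 probes. Pyrethroid exposure at every concentration is argued against for the set as a whole. The cypermethrin 0.56 ug/kg arrays, on other slides, showed a median share of -0.0897 of the shift (SD 0.0859, n = 3). Over the probes this share had quartiles of -0.337 and 0.172, so the median does not speak for each probe. Contig_2633, in the set, differed from control by 1.79 and 1.28 at cypermethrin 0.56 and 1.0 ug/kg. The differences were 2.00 and 1.28 at deltamethrin 0.18 and 0.32 ug/kg, against 0.15 and -0.05 at ammonia 560 and 1000 ug/g. Only that at deltamethrin 0.18 ug/kg passed. A batch shared by slides 4 to 8 stays open: ammonia arrays of slides 4 and 5 showed a median share of 0.729 of the shift against those of slides 2 and 3, with 1.01 on slide 5 alone and 0.315 on slide 4 alone. Against it, cypermethrin 0.56 ug/kg replicate 2, also on slide 4, showed a share of -0.00194 against replicates 1 and 3. For the set as a whole, slides 6 to 8 and exposure to cypermethrin 1.0 ug/kg or deltamethrin cannot be told apart, since no control lay on those slides. The set held all 14 calls of deltamethrin 0.18 ug/kg, and 33 of the 34 rises and all 5 falls of deltamethrin 0.32 ug/kg. It also held all 3 calls between the cypermethrin concentrations and 26 of the 29 at the lower concentrations. Each of these comparisons shares arrays with the choice of the set, so the overlap alone does not tell slide from exposure.

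Among the ammonia arrays, 533 probes differed between slides 2 and 3 and slides 4 and 5, 452 of them higher on slides 4 and 5, with a median shift of 2.00 (596 probes without slide 4, 400 of them shared). Slide as a batch stays open: cypermethrin 0.56 ug/kg replicate 2 on slide 4 departed from its group by 0.185 of that shift, with 65.5% of probes in the same direction. On the log2 scale, and not as a share, the 9 arrays of slides 6 to 8 lay 1.59 to 2.25 from the ammonia arrays of slides 2 and 3. On the same scale the control and cypermethrin 0.56 ug/kg arrays of slides 1 to 3 lay 0.354 to 0.749 from those ammonia arrays. Cypermethrin 0.56 ug/kg replicate 2 lay 1.05 from them. Replicate number 3 as a shared source stays open too, at 0.108 of the shift (0.127 for control and 0.0885 for cypermethrin 0.56 ug/kg). No biological explanation was tested, since both concentrations lay on either side. These probes and the 619, both drawn from the ammonia arrays among others, shared 153, all in the same direction, and 2 of the 42 probes called against control were among the 533.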

How the results depend on the processing

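Alternatives named here as scan day, slides 4 to 8, slide 4 left out, scan day 3 alone and the slide block on slides 6 to 8 alone were chosen after seeing the data. Leaving out 1 array gave 0 to 1 calls for ammonia 560 ug/g, 0 to 17 for deltamethrin 0.18 ug/kg and 25 to 48 for deltamethrin 0.32 ug/kg against control. It gave 0 for cypermethrin 1.0 against 0.56 ug/kg, 6 to 54 for cypermethrin 1.0 against deltamethrin 0.32 ug/kg and 0 to 26 for cypermethrin 0.56 against deltamethrin 0.18 ug/kg. The 14 calls of deltamethrin 0.18 ug/kg became 0 with normexp, quantile normalization, no filter, slide as a random block, replicate block, only the compared groups, scan day and slides 4 to 8, 7 without slide 4 and 538 with array weights. The 39 calls of deltamethrin 0.32 ug/kg became 17 among probes well above background on all 21 arrays, 3636 with array weights, and 0 with scan day and with slides 4 to 8. Array weights also gave 1 call for ammonia 1000 ug/g, 724 for cypermethrin 1.0 ug/kg and 1058 between the deltamethrin concentrations. The estimation of these weights stopped before it converged, with a weight of 35.4 for deltamethrin 0.32 ug/kg replicate 2. Only the compared groups gave 138 calls for cypermethrin 1.0 ug/kg, and scan day gave 1 for ammonia 560 ug/g. The 3 calls between the cypermethrin concentrations became 10 with normexp, 78 with quantile normalization, 0 with no filter, 37 among probes well above background on all arrays, 163 with replicate block, 217 with only the compared groups, 1234 with array weights and 43 with the series table. They became 0 without slide 4, with scan day 3 alone and with slides 4 to 8, and scan day gave 2 others, both lower. The 54 probes between the pyrethroids at the higher concentrations became 35 with normexp, 19 among probes well above background on all arrays, 0 with only the compared groups, 2340 with array weights, 0 with scan day 3 alone and 0 with slide as a fixed block on slides 6 to 8 alone. That last model, run before the fixed block over all 21 arrays (60 calls, 51 shared), uses fewer arrays. The 29 probes at the lower concentrations became 0 with normexp, 7 with no filter, 15 among probes well above background on all arrays, 61 with replicate block, 695 with array weights, 16 without slide 4, 0 with scan day 3 alone and 3 with slides 4 to 8. Scan day 3 held 1 array on one side of each of these 3 comparisons, which was assumed to vary like the other groups, so its counts of 0 say nothing about stability. With normexp, contig_5972 for ammonia 560 ug/g turned to -0.0487, contig_2089 between the ammonia concentrations to 0.0212, and the correlation between cypermethrin 0.56 and deltamethrin 0.18 ug/kg to -0.2247. Apart from the fewer probes or arrays of a filter or a subset, the cause was not tested. The other counts of 0 stayed at 0. The named contigs of deltamethrin 0.32 ug/kg kept their direction in every alternative that gave a value, and contig_5795 and contig_4390 passed in 9 of 11 alternatives and without any 1 array. The fallen contig_8058 and contig_5396 also passed without any 1 array, but in 7 of 11 and 8 of 12 alternatives: neither passed with normexp, only the compared groups, scan day or slides 4 to 8, and contig_8058 ranged from -2.31 to -0.47. Probes that are dim on some arrays are limited by signal over background, since 2309 of the 7922 tested probes were well above background on all 21 arrays. A fixed slide block gave no value between slides 1 to 3 and slides 6 to 8, a single scan day none where it held 1 side, and a filtered probe none. The set test and gene lists were not run.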

Other observations

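The tests in this part were chosen after the result was seen. Of the 54 probes lower in cypermethrin 1.0 than in deltamethrin 0.32 ug/kg, 25 from 16 contigs were not called against control in deltamethrin 0.32 ug/kg. Their medians on the cypermethrin 1.0 ug/kg arrays, relative to the control mean, were 0.13, -5.33 and -3.31 in replicates 1, 2 and 3, and their group mean was 3.37 ± 0.25 (SD, n = 3) at deltamethrin 0.32 ug/kg. By fold change, 33 of the 54, which were chosen on the same cypermethrin arrays, were lower in cypermethrin 1.0 ug/kg than in control, and all 54 were higher in deltamethrin 0.18 ug/kg than in control, where 9 of the 34 risen probes passed the test.

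Probes with neighbouring serial numbers in the first of the 3 probe sets of the design moved together. Over 1077 pairs of adjacent probes from different contigs the mean correlation across arrays was 0.151, and 5.29% of pairs exceeded 0.8. Group means were not removed, so differences between groups enter these correlations. The mean was 0.0265 at a distance of 50 and 0.0253 at a distance of 500, and it spanned -0.00641 to 0.0520 over 1000 random orders. Adjacent probes gave 0.0696 in the second set and 0.0335 in the third. Neighbouring numbers may mark contigs of related transcripts, a hypothesis that would make contigs less than separate evidence, and 29 of the 34 probes that rose at deltamethrin 0.32 ug/kg came from the first set, which holds 48.3% of tested probes.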
